A study of Sus scrofa with 9 samples.

How the data were processed

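Gene expression in pig liver was measured by RNA sequencing in 9 animals, 4 MIDY and 5 WT, which were grouped by the genotype given in the labels. Each library is labelled as a separate animal, so the spread between libraries is that between pigs, but litter, pen, sampling day and sequencing batch were not used here. Per the labels' protocols, RNA was isolated with Trizol and libraries were prepared from ribosomally depleted total RNA with the Encore Complete kit of Nugen. Reads were aligned with STAR and counted with HTSeq, per the submitters' processing notes, which also name DESeq2 and the genome build Sscrofa11.1. Versions, aligner settings, the annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited raw counts per gene symbol, not normalized, in a table with 1 column per library. The values are whole numbers whose sums differ between libraries.

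The strand setting decides whether reads of overlapping genes on opposite strands can be told apart, so overlapping genes are given as uncertain. Reads that fit several near-identical genes are often left out or split by counting tools, which makes levels of close copies uncertain. All 29837 symbols of the table matched the RefSeq gene table of Sscrofa11.1, from which positions and gene types were taken. Of these symbols, 12908 are LOC names. In all, 7940 symbols had 0 counts in all libraries. The table held 0 entries that name no gene and 0 unused columns. RN18S, a ribosomal RNA gene, took 6.96 to 11.4% of the counts per library, and the 10 most abundant genes 30.9 to 35.3%.

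Depth was 14115415 to 19533463 counts per library. Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr on the group, which kept 14100 genes with 99.9% of the counts, scaled with TMM factors and fitted with the robust quasi-likelihood model. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p below 0.05 with no threshold on fold change. Every edgeR or limma voom adjusted p in the text is of this kind. DESeq2 calls use its own adjusted p, which was missing for 278 of the 14100 genes. A standard error of a log2 fold change is the fold change divided by the square root of its F statistic. Levels are CPM, counts divided by the TMM-scaled library size and multiplied by 1e6. The common biological coefficient of variation was 21.5%.

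Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01 between genes, adjusted over the 38 lists with at least 3 tested members. The test was repeated with the correlation estimated per list and with fry, whose directional p asks whether a list's genes move one way on balance. For each list the members called over all genes, and the members called when adjusted over the list alone, were counted. The adjustment over the list alone makes no correction for the number of lists. The lists cover glucose, glycogen, fatty acid, ketone, cholesterol, bile acid, urea, amino acid, retinoid, xenobiotic and lipoprotein metabolism, the insulin and IGF axis, stress, clock, hypoxia, interferon, acute phase, matrix and cell cycle genes, and markers of liver cell types and of cells that could be carried in. A list score is the mean log2 CPM of its genes in a library, and scores were compared by exact two-sided permutation over all 126 splits of the 9 libraries, whose smallest p is 0.00794. Without WT replicate 2 there are 70 splits, with a smallest p of 0.0286.

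Genes named in the text follow a rule. The first part takes the 12 genes higher and the 12 lower with the largest absolute log2 fold change among called genes with a symbol, a mean of at least 1 CPM over the libraries and no overlap between the groups; 99 higher and 45 lower genes could be chosen from. The second part takes of each described list up to 4 tested members with the smallest p, and up to 4 more called members in a list with more than 8 called, which no list had. The third part fixes genes of insulin action and liver metabolism, INS, PCK1, G6PC, IGFBP1, RDH16, SREBF1, FASN and CYP7A1 among them. Some genes that the rule names are not reported here. The groups, the main tests, the 40 gene lists, the naming rule and the alternatives were fixed before the data were examined, except for the alternatives and tests said to be chosen later.

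The alternatives were RLE size factors, total counts alone, the 10 most abundant genes taken out, no low-count filter, a stricter filter (at least 1 CPM in at least 4 libraries), DESeq2 1.42.0, limma voom with sample weights, 1 surrogate variable from sva 3.50.0 as a covariate, and leaving out each library in turn. Leaving out WT replicates 1 and 2 together, which stood apart from the other WT libraries on principal components, was added after seeing the data, as was total-count scaling for the lists. No replicate numbers pair the 2 groups, so no paired fit was made. The fits were tested on simulated data with counts drawn for the 14100 genes of the MIDY and WT comparison. There edgeR recovered 13.4% of 67 genes changed 1.5-fold, 74.6% of 67 genes changed 2-fold and 84.8% of 66 genes changed 4-fold, with 9 false calls among 124. DESeq2 made 25 false calls among 151 and voom 2 among 113. Camera called 0 of 38 lists in simulated data with no change and only the shifted list in data with 1 shifted list, but genes were simulated as independent, so this did not test the effect of correlated genes.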

Results

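Liver transcriptomes were compared between 4 MIDY pigs and 5 wild type (WT) pigs, all female and 2 years old. MIDY stands for mutant INS gene-induced diabetes of youth, and these animals carry a transgene with a mutated insulin gene. Diabetic pigs received insulin, per the labels, so genotype and insulin treatment cannot be separated in this design. Each library was made from the total RNA of 1 liver after ribosomal depletion, and the deposited table gives raw read counts for 29837 gene symbols. MIDY libraries 1 to 4 held 16926123, 14819335, 18708976 and 17279084 counts, and WT libraries 1 to 5 held 14115415, 19533463, 16109916, 15929324 and 17223174. Total counts, genes detected, the shares of RN18S, of the 10 most abundant genes and of long non-coding RNA, and the scaling factor passed no test for a difference between the groups (exact two-sided permutation tests over 126 splits, lowest adjusted p = 0.571 over 6 measures). The INS gene itself had 3 counts over the MIDY libraries and 2 over the WT libraries, with at most 2 in any library, a level that cannot check the genotype labels in liver. On the first principal component of the 500 most variable genes, which held 32.3% of their variance, all 4 MIDY libraries lay above all 5 WT libraries (6.51 for the lowest MIDY library, 0.90 for WT replicate 1 as the highest WT library, exact permutation p = 0.0159).

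The comparison of MIDY with WT liver asks which transcripts differ in animals with this form of diabetes. Among the transcripts that rose most in MIDY liver were CYP8B1, SDS and GPT2. CYP8B1, the sterol 12-hydroxylase of bile acid synthesis, rose from 0.190 ± 0.176 (SD, n = 5) to 14 ± 13 CPM (SD, n = 4). SDS, which deaminates serine and threonine, rose by 2.24 ± 0.36 on the log2 scale and GPT2, the mitochondrial alanine aminotransferase, by 1.74 ± 0.23 (log2 ± SE; edgeR adjusted p = 0.0273 and 0.00696). Among transcripts that fell, CRP, the C-reactive protein of the acute phase, went from 306 ± 90.3 (SD, n = 5) to 112 ± 23.4 CPM (SD, n = 4), and PFKFB3, which makes the activator of glycolytic phosphofructokinase, fell from 6.75 ± 1.69 (SD, n = 5) to 2.53 ± 0.43 CPM (SD, n = 4).

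Of 14100 genes tested with edgeR's quasi-likelihood test, 115 rose and 50 fell in MIDY liver at a Benjamini-Hochberg adjusted p below 0.05, so 69.7% of the 165 called genes rose. At an unadjusted p below 0.05 there were 2277 genes. The fold change was 2 or more for 43 of the genes that rose and for 15 of those that fell. In 160 of the 165 called genes the levels of the 2 groups did not overlap. Such a separation was seen in 896 tested genes, or 6.35%, where chance gives 1.59%. Protein-coding genes made up 153 of the calls and long non-coding RNAs 11. All 165 were also called by DESeq2, which called 355 genes higher and 284 lower, so that 55.6% of its calls were higher. It used the same counts and made more false calls in simulated data (25 among 151, against 9 among 124 for edgeR). The overlap therefore adds little support. The number of called genes depended on single libraries: it was 38 without MIDY replicate 2, 53 without MIDY replicate 3, 259 without WT replicate 1, 59 without WT replicate 2, 81 without WT replicate 3, 80 without WT replicate 4 and 60 without WT replicate 5.

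**Figure D1:**
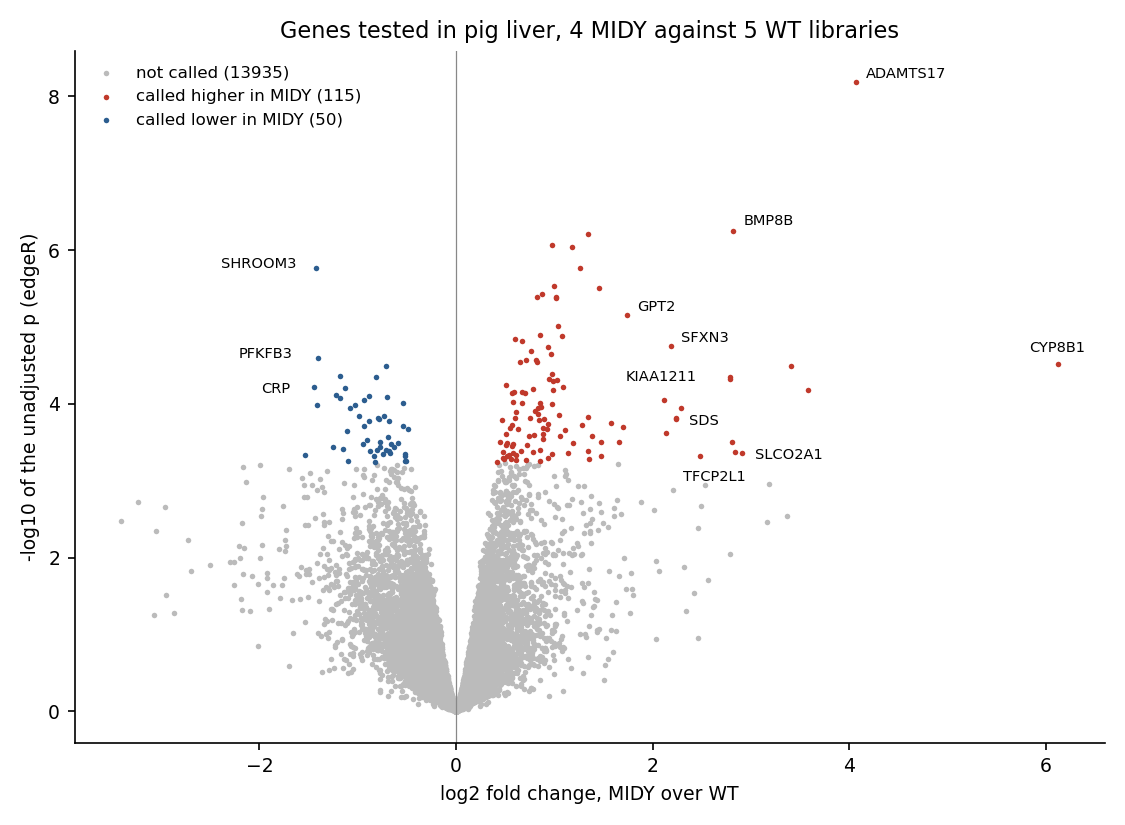
Each point is 1 of the 14100 tested genes, with the log2 fold change of MIDY over WT on the x axis and minus log10 of the unadjusted edgeR p on the y axis; red and blue points are the 115 genes called higher and the 50 called lower. Among the called genes CYP8B1 has the largest log2 fold change (6.12), and ADAMTS17 (log2 fold change 4.07) has the smallest p.

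Among the 12 genes with the largest rise under the naming rule were CYP8B1, ADAMTS17, SLCO2A1, BMP8B, KIAA1211, TFCP2L1, SDS, SFXN3, SLC25A47, GPT2 and RHPN1. CYP8B1 (chromosome 13, 26330233 to 26331738, on Sscrofa11.1) had the largest log2 fold change, 6.12 ± 0.80 (SE; edgeR adjusted p = 0.0146). Its level in WT was close to the detection floor, with raw counts of 5, 8, 2, 1 and 0 in the 5 WT libraries against 537, 140, 137 and 108 in the 4 MIDY libraries, so the size of its fold change is imprecise. Without WT replicates 1 and 2 the rise of CYP8B1 was not called (edgeR adjusted p = 0.0597). ADAMTS17, a secreted metalloprotease gene (chromosome 1, 138619701 to 139015681), had the lowest adjusted p of all genes, 9.2e-05, and rose from 0.298 ± 0.128 CPM (SD, n = 5) to 5.04 ± 0.30 CPM (SD, n = 4; log2 fold change 4.07 ± 0.30 SE; edgeR). SDS lies on chromosome 14 (38503922 to 38513908) and GPT2 on chromosome 6 (37625428 to 37669695). SLC25A47, a mitochondrial carrier gene, rose from 37.0 ± 10.1 to 162 ± 95.4 CPM (SD, n = 5 and 4; edgeR adjusted p = 0.0336), and SLCO2A1, a prostaglandin transporter gene, from 1.66 ± 0.68 to 12.6 ± 9.67 CPM (SD, n = 5 and 4; edgeR adjusted p = 0.0436). SLCO2A1 was called in 1 and TFCP2L1 in 2 of the 9 fits that left out a library, SDS and SLC25A47 in 4 and RHPN1 in 3, while CYP8B1, ADAMTS17, GPT2, SFXN3 and BMP8B were called in all 9. BMP8B rose by 2.82 ± 0.31 on the log2 scale and its close copy BMP8A, named here after its values were seen, by 2.79 ± 0.46 (SE; edgeR adjusted p = 0.00257 and 0.0182); reads can be split between such copies, so each value is uncertain. Counts of CYP8B1, BMP8B and KIAA1211 are likewise uncertain because other gene models overlap them. ZNF662, whose span covers CYP8B1, had a log2 fold change of 0.20 (edgeR adjusted p = 0.653).

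The 12 genes with the largest fall under the naming rule were CRP, SHROOM3, VIL1, PFKFB3, BLNK, MEGF9, SFRP1, GIPC2, CYP26A1, MOB3B, PIGR and TAGAP. CRP (chromosome 4, 90782741 to 90785051) had a log2 fold change of -1.45 ± 0.23 and SHROOM3, an actin-binding protein gene (chromosome 8, 72097561 to 72443869), one of -1.42 ± 0.17 (SE; edgeR adjusted p = 0.0202 and 0.00346). The reference lists 2 copies of the CRP symbol, so its counts are uncertain. CYP26A1, which degrades retinoic acid, fell from 16.3 ± 4.49 to 7.36 ± 2.24 CPM (SD, n = 5 and 4; edgeR adjusted p = 0.0425). SFRP1, a secreted Wnt antagonist, fell by 1.18 ± 0.20 and PIGR, the receptor that carries polymeric immunoglobulin across epithelia, by 1.11 ± 0.21 on the log2 scale (SE; edgeR adjusted p = 0.0217 and 0.0319). BLNK, a B-cell receptor adaptor, and TAGAP, expressed in activated T cells, fell at levels of a few CPM, from 2.16 ± 0.29 to 0.90 ± 0.21 and from 4.09 ± 0.19 to 1.92 ± 0.42 (SD, n = 5 and 4). Other gene models overlap SHROOM3, VIL1, BLNK and MOB3B, which makes their counts uncertain. The overlapping genes USP37 (at VIL1) and ZNF518A (at BLNK) had log2 fold changes of 0.04 and 0.10 (edgeR adjusted p = 0.915 and 0.741). CYP26A1, BLNK and PIGR were each called in 2 of the 9 fits that left out a library, VIL1 and SFRP1 in 3, TAGAP in 4, and SHROOM3 and PFKFB3 in all 9.

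**Figure D2:**
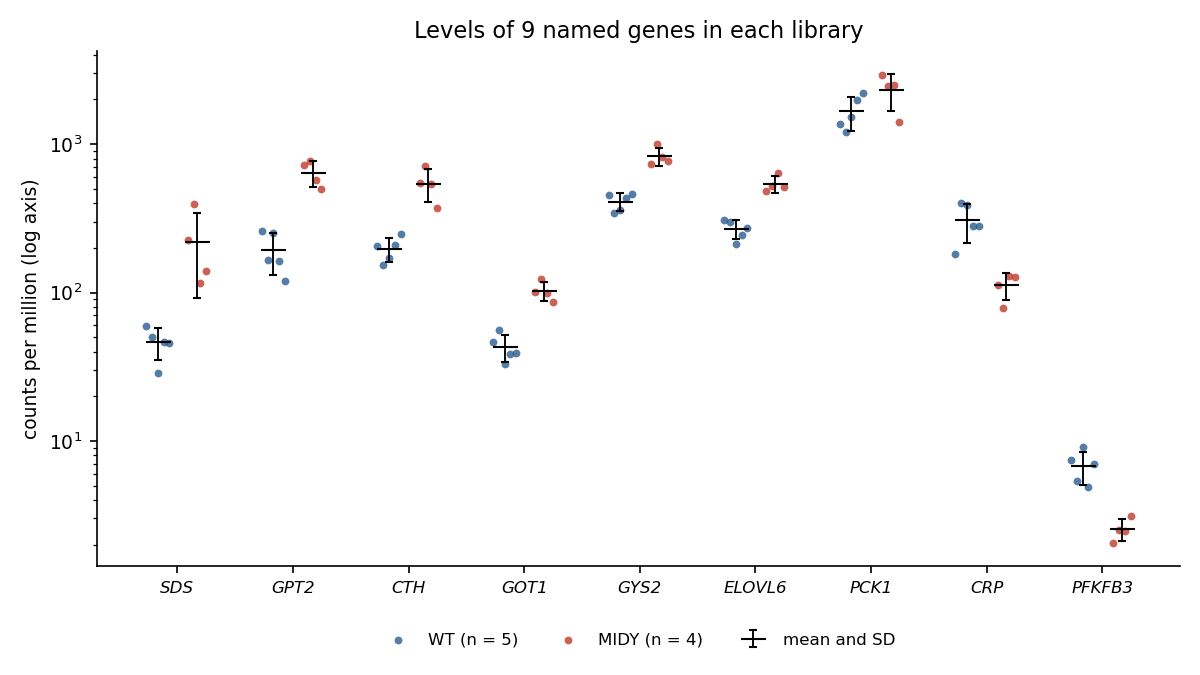
CPM (log axis) of 9 named genes in each WT library (blue) and each MIDY library (red), with the mean and SD of each group in black. SDS, GPT2, CTH, GOT1, GYS2 and ELOVL6 do not overlap between the groups and are higher in MIDY, CRP and PFKFB3 are lower, and PCK1 (edgeR adjusted p = 0.319) overlaps.

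Transcripts of a part of the enzymes that break down amino acids and dispose of their nitrogen rose in MIDY liver. Of 37 measured amino acid catabolism genes, 8 rose and 0 fell over all genes tested, and 15 rose and 1 fell when adjusted over the list alone. CTH, which makes cysteine from cystathionine, rose from 197 ± 36.8 to 542 ± 137 CPM, and GOT1, the cytosolic aspartate aminotransferase, from 42.7 ± 8.76 to 102 ± 14.8 CPM (SD, n = 5 and 4; edgeR adjusted p = 0.00451 and 0.00346). HGD, of tyrosine breakdown, rose by 0.98 ± 0.16 on the log2 scale (SE; edgeR adjusted p = 0.0182). In the urea cycle and ammonia list, ARG1 (1.28 ± 0.24), ASS1 (0.81 ± 0.13) and GLS2 (0.68 ± 0.10) rose among 11 measured genes, and none fell (log2 ± SE; edgeR adjusted p = 0.0302, 0.0144 and 0.0114). Adjusted over the list alone, 7 urea cycle and ammonia genes rose and 2 fell. Those 2 were GLUL, which makes glutamine from ammonia, and NAGS, named here after their values were seen, with log2 fold changes of -0.98 and -0.39. Of 13 measured markers of periportal hepatocytes, those nearest the portal vein, 6 rose (SDS, ARG1, HAL, ASS1 and GLS2 among them) and 7 rose when adjusted over the list alone. The periportal list shares 6 genes with the amino acid and urea lists, so the 3 are not independent. The pericentral list, for hepatocytes nearest the central vein, was not called (camera adjusted p = 0.732): of 15 markers only TBX3 rose (0.93 ± 0.18 log2, SE; edgeR adjusted p = 0.0310), and 2 rose and 3 fell adjusted over the list alone. GLUL is among these 15 markers and OAT is shared with the amino acid list, so the pericentral list is not independent either. Camera called the amino acid (median log2 fold change 0.31, adjusted p = 3.5e-09), periportal (0.57, 3.6e-09) and urea (0.45, 2.8e-04) lists higher. All 3 had an adjusted p = 0.246 with an estimated correlation. The 8 amino acid genes over all genes became 4 without MIDY replicate 2, WT replicate 2 or WT replicate 4 and 5 without WT replicate 3, and the 6 periportal genes became 3 without WT replicate 2 or WT replicate 3. Of the genes named here CTH, GOT1, ASS1 and GLS2 were called in all 9 fits that left out a library, HGD in 8, ARG1 and HAL in 5 and TBX3 in 4. Fewer than 2 urea cycle and ammonia genes fell adjusted over the list alone in 6 of the 9. For the pericentral list, 1 gene in place of 3 fell adjusted over the list alone without MIDY replicate 1 or MIDY replicate 2 and 5 without WT replicate 5. The 1 amino acid gene that fell adjusted over the list alone became 0 without MIDY replicate 1, MIDY replicate 2, WT replicate 4 or WT replicate 5 and 3 without MIDY replicate 4. Over all genes 2 pericentral genes rose without MIDY replicate 4, and 2 pericentral genes fell without WT replicate 1 and 1 fell without MIDY replicate 4.

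In the lists of fat oxidation and glucose output few genes were called singly. Camera called the mitochondrial fatty acid oxidation list higher (median log2 fold change 0.21, adjusted p = 0.00334), with 0 of 20 measured members called over all genes and 0 adjusted over the list alone. That list had an adjusted p = 0.459 with an estimated correlation, and its fitted values were above 0 for 17 of the 20, HADHA (0.51 ± 0.18) and CPT2 (1.14 ± 0.45, log2 ± SE) among them. In the list of peroxisomal oxidation and PPARA targets, CREB3L3 rose (0.72 ± 0.15 log2, SE; edgeR adjusted p = 0.0394) and 5 of 18 members rose adjusted over the list alone, PDK4, PPARA and ACAA1 included (0.71, 0.74 and 0.56 log2). Camera called it higher (median 0.25, adjusted p = 0.00449; adjusted p = 0.246 with an estimated correlation). In the gluconeogenesis and glucose output list, FBP1 rose from 235 ± 38.5 to 438 ± 102 CPM (SD, n = 5 and 4; edgeR adjusted p = 0.0273), and 2 of 8 members rose adjusted over the list alone. Camera called that list higher too (median 0.39, adjusted p = 0.00848; adjusted p = 0.416 with an estimated correlation). PCK1, the cytosolic enzyme that opens gluconeogenesis from oxaloacetate, was not called, at 1664 ± 429 CPM in WT and 2320 ± 642 CPM in MIDY (SD, n = 5 and 4; edgeR adjusted p = 0.319). G6PC, which releases free glucose, was not called either (-0.23 ± 0.39 log2, SE; edgeR adjusted p = 0.834). Without MIDY replicate 1, neither the fatty acid oxidation nor the gluconeogenesis list was called (camera adjusted p = 0.0888 for both). CREB3L3 was called in 2 and FBP1 in 3 of the 9 fits that left out a library (edgeR adjusted p up to 0.114 and 0.0860). Without MIDY replicate 4 the counts adjusted over the list alone were 4 for fatty acid oxidation and 4 for gluconeogenesis. Over all genes 2 peroxisomal and PPARA genes rose without MIDY replicate 4 or WT replicate 1 and 2 gluconeogenesis genes without WT replicate 1. In the peroxisomal list 1 gene fell adjusted over the list alone without MIDY replicate 2, MIDY replicate 4 or WT replicate 3.

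Glucose storage and lipid synthesis genes moved singly. GYS2, the liver glycogen synthase, rose from 410 ± 55.8 to 831 ± 115 CPM, and ELOVL6, which elongates C16 fatty acids, from 267 ± 39.2 to 541 ± 70.2 CPM (SD, n = 5 and 4; edgeR adjusted p = 0.00451 for both). Each was the only called gene of its list: 1 of 16 glycogen genes rose (also 1 adjusted over the list alone) and 1 of 20 fatty acid and triglyceride synthesis genes rose (2 rose and 1 fell adjusted over the list alone). The lipogenic regulator SREBF1 (-0.69 ± 0.26) and the synthase FASN (0.60 ± 0.37) were not called (log2 ± SE; edgeR adjusted p = 0.232 and 0.472). In glycolysis, LDHA rose (0.75 ± 0.14) and PFKFB3 fell (-1.41 ± 0.22 log2, SE; edgeR adjusted p = 0.0273 and 0.0144) among 14 genes, with 2 up and 2 down adjusted over the list alone. Of 20 insulin and IGF axis genes, IGFALS, which holds IGF in its circulating complex, fell (-0.82 ± 0.13 log2, SE; edgeR adjusted p = 0.0182). Adjusted over the list alone 1 gene of that list rose (INSR, 0.42 ± 0.10) and 1 fell. IGFBP1, a liver transcript repressed by insulin, was not called (-0.14 ± 0.27; edgeR adjusted p = 0.862). Camera called none of these 5 lists: adjusted p was 0.384 for glycogen (median 0.08), 0.937 for lipid synthesis (median -0.06), 0.931 for glycolysis (median 0.04), 0.470 for ketone bodies (median 0.16) and 0.931 for the insulin and IGF axis (median -0.08). For lipid synthesis the median and mean lay below 0 and camera's direction above 0, and for glycolysis only the mean lay below 0. GYS2 and ELOVL6 were called in all 9 fits that left out a library, IGFALS in 8 and LDHA in 5. In the lipid synthesis list 2 genes rose over all genes without MIDY replicate 4 and 1 fell without MIDY replicate 3 or WT replicate 2. When adjusted over the list alone 3 lipid synthesis genes fell without MIDY replicate 3 and 2 without WT replicate 1, WT replicate 2 or WT replicate 4. For glycolysis, adjusted in the same way, 1 rose without MIDY replicate 1 or MIDY replicate 2, and 1 fell without MIDY replicate 2, MIDY replicate 3, WT replicate 3 or WT replicate 5. The glycogen count became 2 without MIDY replicate 4, and in the insulin and IGF list 2 rose without MIDY replicate 4 or WT replicate 1 and 2 fell without MIDY replicate 3, over all genes as well. IGFALS lost its call without MIDY replicate 2.

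Camera called lists of extracellular matrix, antigen presentation and lymphocyte genes lower in MIDY liver, with few genes called singly. In the extracellular matrix list, MGP (from 24.8 ± 1.65 to 12.9 ± 4.44 CPM) and COL1A2, a chain of type I collagen (from 60.1 ± 10.3 to 34.3 ± 8.03 CPM), fell over all genes (SD, n = 5 and 4; edgeR adjusted p = 0.0303 and 0.0434). Adjusted over the list alone 13 of 37 matrix genes fell and 0 rose, COL1A1 (-1.05 ± 0.25) and COL6A2 (-0.63 ± 0.17 log2, SE) included. In the list of interferon response and antigen presentation, 2 genes of the MHC class II pathway fell, SLA-DQA1 (-0.78 ± 0.15) and CD74 (-0.74 ± 0.16 log2, SE; edgeR adjusted p = 0.0273 and 0.0444), and 5 of 36 fell adjusted over the list alone, all of them antigen presentation genes (with SLA-DQB1, SLA-2 and SLA-DRA, the last named after its values were seen). SLA genes are a family of similar copies and their counts are uncertain. CD2, a surface molecule of T and NK cells, fell from 9.07 ± 2.12 to 4.86 ± 0.42 CPM (SD, n = 5 and 4; edgeR adjusted p = 0.0377), the only 1 of 18 T and NK markers called, over all genes or adjusted over the list alone. No B and plasma cell marker of 8 was called either way (JCHAIN -0.86 ± 0.29 log2, SE). Camera called the matrix (median -0.38, adjusted p = 2.7e-10), interferon (-0.66, 2.3e-09), T and NK (-0.60, 1.1e-04) and B and plasma cell (-0.70, 0.0204) lists lower. With an estimated correlation the matrix, T and NK and B and plasma cell lists had an adjusted p = 0.246, and the interferon list had an adjusted p = 0.416 with an estimated correlation. WT replicate 2 stood apart: its T and NK score was 0.74 above the mean of the 9 libraries on the log2 scale, against 0.04 to 0.16 in the other WT libraries and -0.35 to -0.23 in MIDY. Its interferon score was the highest as well, at 0.94 against -0.10 to 0.35 in the other WT libraries. The check of within-group gaps given below flagged the T and NK score but not the interferon score. Without WT replicate 2 the interferon median was -0.40 in place of -0.66. The calls of single genes here rested on all libraries: SLA-DQA1 was called in 3, MGP, COL1A2 and CD2 in 2 and CD74 in 1 of the 9 fits that left out a library. The B and plasma cell list was not called without WT replicate 1 (camera adjusted p = 0.0568). The 13 matrix genes adjusted over the list alone became 6 without MIDY replicate 1, 8 without MIDY replicate 2 and 21 without MIDY replicate 4. They became 21 without WT replicate 1, 7 without WT replicate 2 and 8 without WT replicate 3. The 5 interferon genes became 2 without MIDY replicate 1, 18 without MIDY replicate 2 and 13 without WT replicate 1. They became 3 without MIDY replicate 3, MIDY replicate 4, WT replicate 2 or WT replicate 3. The 1 T and NK gene adjusted over the list alone became 3 without WT replicate 1, 4 without WT replicate 3 and 2 without WT replicate 5, where 2 B and plasma cell markers fell too. Over all genes 5 matrix genes fell without MIDY replicate 4 and 5 interferon genes without WT replicate 1. In the interferon list 1 gene rose adjusted over the list alone without MIDY replicate 4. With total-count scaling 0 matrix genes fell over all genes and 6 adjusted over the list alone. There MGP had a log2 fold change of -0.90 ± 0.22 against -0.94 ± 0.18 and COL1A2 one of -0.77 ± 0.20 against -0.81 ± 0.17 (SE; edgeR adjusted p = 0.0851 and 0.0965), so the spread grew more than the change shrank.

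**Figure D3:**
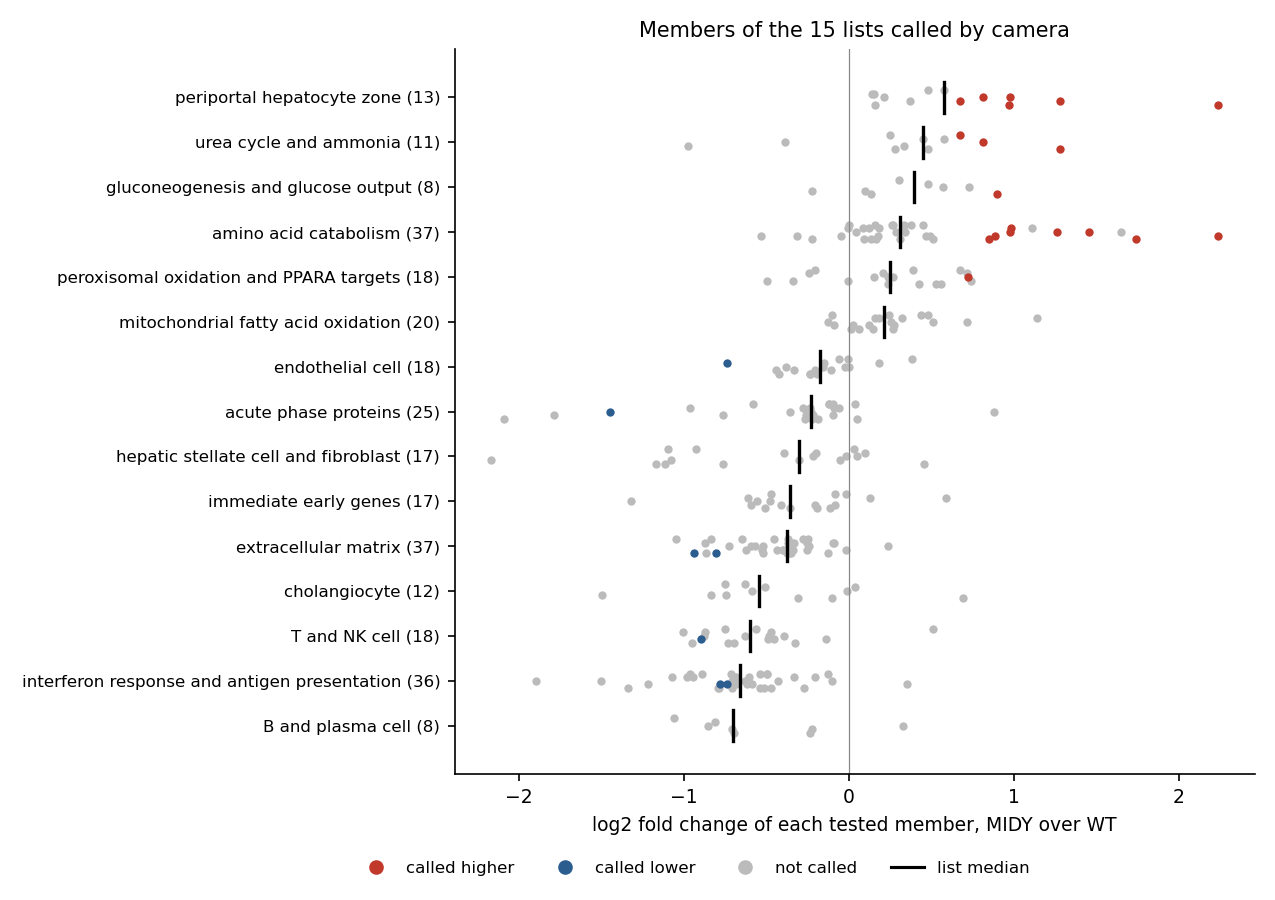
Log2 fold change of each tested member of the 15 lists called by camera, with the number of members in brackets; red and blue points were called over all genes, grey points were not, and black lines are list medians. The medians run from -0.70 for B and plasma cell markers to 0.57 for periportal markers, and most members are not called singly.

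Of markers of other liver cell types, hardly any was called singly. EMCN was the only called gene of 18 endothelial markers (-0.74 ± 0.14 log2, SE; edgeR adjusted p = 0.0273). Adjusted over the list alone FLT1 fell too and STAB2, a sinusoidal scavenger receptor, rose (0.38 ± 0.12 log2, SE). Over all genes neither FLT1 nor STAB2 was called (edgeR adjusted p = 0.0796 and 0.144). No stellate cell and fibroblast marker of 17 was called either way, with fitted values of -1.12 ± 0.38 for the smooth muscle actin ACTA2 and -0.76 ± 0.25 for DES (log2 ± SE). Of 12 cholangiocyte markers 0 were called over all genes and 1, PKHD1, fell adjusted over the list alone (-0.75 ± 0.19 log2, SE). Of 25 acute phase genes CRP fell, over all genes and adjusted over the list alone, whereas ORM1 (-0.58 ± 0.17 log2, SE) was not called. Of 17 immediate early genes 0 were called either way (JUN -0.51 ± 0.19 log2, SE). Camera called all 5 lists lower, endothelial (median -0.18, adjusted p = 0.0133), stellate (-0.30, 0.00847), cholangiocyte (-0.55, 0.0461), acute phase (-0.23, 0.00182) and immediate early (-0.36, 0.0204). The endothelial, acute phase and immediate early lists had an adjusted p = 0.416, 0.459 and 0.416 with an estimated correlation, and the stellate and cholangiocyte lists an adjusted p = 0.347 and 0.585 with an estimated correlation. The cholangiocyte list lost its call without MIDY replicate 1, MIDY replicate 2, WT replicate 2, WT replicate 4 or WT replicate 5 (camera adjusted p = 0.134, 0.117, 0.120, 0.149 and 0.0518). The immediate early list lost it without MIDY replicate 3 or WT replicate 4 (0.103 and 0.0939), the acute phase list without MIDY replicate 4 (0.0577) and the endothelial list without WT replicate 3 (0.0631). EMCN was called in 3 and CRP in 8 of the 9 fits that left out a library. Of the acute phase genes 4 fell adjusted over the list alone without MIDY replicate 1, 2 without WT replicate 1 and 3 (with 1 that rose) without WT replicate 2. The rise of STAB2 adjusted over the list alone was kept only without MIDY replicate 4 or WT replicate 1, and the cholangiocyte count was 0 without MIDY replicate 1, MIDY replicate 2 or MIDY replicate 3 and 2 without MIDY replicate 4 or WT replicate 1. Over all genes 2 cholangiocyte markers fell without MIDY replicate 4 and 1 without WT replicate 1. JUN was called without MIDY replicate 4 (-0.74 ± 0.16 log2, SE; edgeR adjusted p = 0.0468), and adjusted over the list alone 1 immediate early gene fell without MIDY replicate 1 or MIDY replicate 4. Without MIDY replicate 2, 1 endothelial marker in place of 2 fell adjusted over the list alone. Kupffer cell and macrophage (median -0.20, camera adjusted p = 0.0680), neutrophil (-0.63, 0.0890), erythroid (-1.15, 0.685) and hepatocyte markers (-0.02, 0.931) were not called as lists with all libraries and held 0 called genes. In the 9 fits that left out a library, the Kupffer cell and neutrophil lists were each called lower in 3 (lowest camera adjusted p = 0.00948 and 0.00422). The erythroid and hepatocyte lists were called in 0 of those fits. Adjusted over the list alone, 1 neutrophil marker fell (CXCR2; 2 without MIDY replicate 1 or WT replicate 1) and none of the other 3 lists changed. Leaving out 1 library gave single calls in those 3, adjusted in the same way: a Kupffer cell marker higher without WT replicate 1, which was also called over all genes, and lower without WT replicate 3, a hepatocyte marker higher without MIDY replicate 3 or WT replicate 5, and an erythroid marker lower without WT replicate 4.

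**Figure D4:**
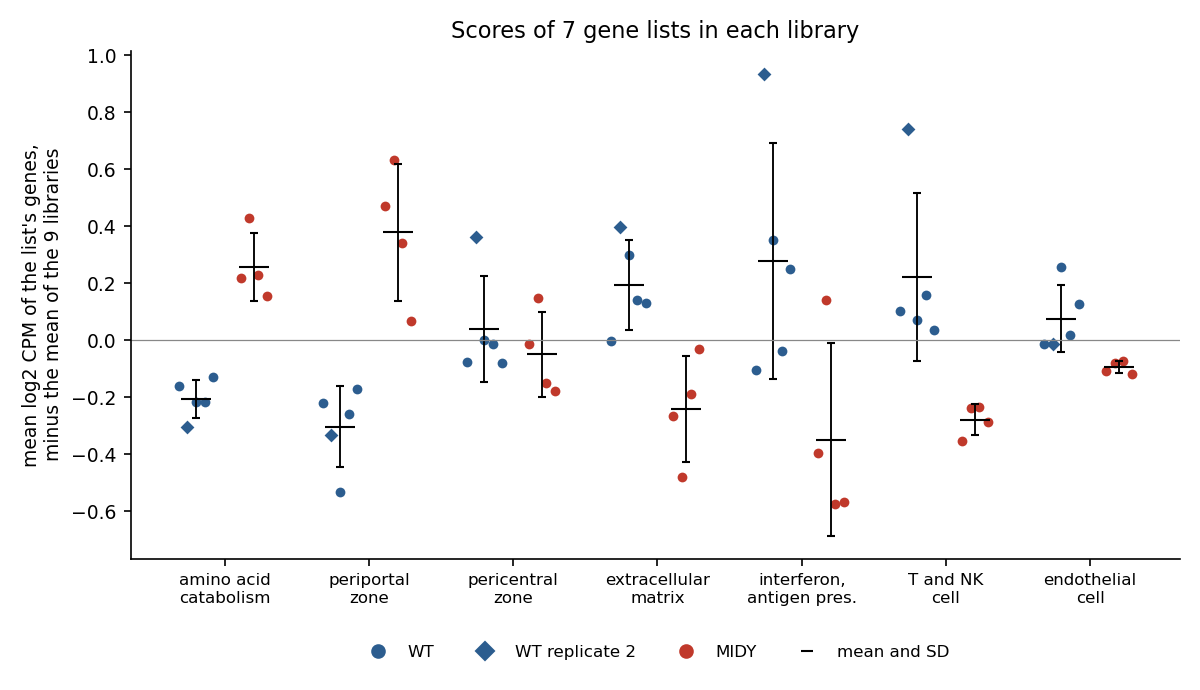
Score of 7 lists in each library, as the mean log2 CPM of the list's genes minus the mean of the 9 libraries, for WT (blue, replicate 2 as a diamond) and MIDY (red), with the mean and SD of each group in black. The groups overlap for the pericentral zone and the interferon list and for none of the other 5, and WT replicate 2 has the highest T and NK score (0.74).

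The remaining lists were not called by camera with all libraries. In the 9 fits that left out a library, it called the cell cycle list in 3 (lowest camera adjusted p = 0.0196). There it also called oxidative phosphorylation in 2 and antioxidants in 1 (lowest camera adjusted p = 0.0308 and 0.0499). Over all genes, 1 gene rose in each of the bile acid (CYP8B1, of 14), hypoxia (BNIP3, 0.51 ± 0.09 log2, SE, of 12), xenobiotic metabolism (SULT2A1, 0.88 ± 0.17, of 29) and stress response (CREB3L3, of 22) lists, and RDH11 rose (1.04 ± 0.15) and CYP26A1 fell among 20 retinoid metabolism genes. RDH16, a retinol dehydrogenase of liver, was not called (0.75 ± 0.20 log2, SE; edgeR adjusted p = 0.0897), nor was CYP7A1, the rate-limiting enzyme of bile acid synthesis (-1.14 ± 0.84; edgeR adjusted p = 0.556). The counts adjusted over the list alone were 1 up and 0 down for bile acids, 3 up and 1 down for hypoxia, 3 up and 2 down for xenobiotic metabolism, 1 up and 1 down for stress response, and 2 up and 2 down for retinoids. Of these genes RDH11 was called in all 9 fits that left out a library, BNIP3 in 5 and SULT2A1 in 2. The 3 hypoxia genes became 1 without MIDY replicate 3 or WT replicate 3, and the 1 that fell became 0 without MIDY replicate 3. For xenobiotics 1 gene in place of 2 fell adjusted over the list alone in all fits without 1 library but those without MIDY replicate 1 or WT replicate 4. For retinoids 1 rose without MIDY replicate 2 or MIDY replicate 3, and 1 fell without MIDY replicate 1, MIDY replicate 2, MIDY replicate 3, WT replicate 2 or WT replicate 4. For stress response 2 fell without MIDY replicate 1 and 0 without MIDY replicate 2 or MIDY replicate 3. Lipoprotein genes (2 up adjusted over the list alone, APOA4 and APOA5, and 0 without MIDY replicate 1, MIDY replicate 2, WT replicate 3 or WT replicate 5, 4 without MIDY replicate 4 and 1 without WT replicate 4) and adipocyte and muscle markers (1 up, 1 down) held 0 genes called over all genes. Leaving out 1 library also gave these calls over all genes. For xenobiotics 2 rose without MIDY replicate 4 and 1 fell without MIDY replicate 1, and for retinoids 2 rose without WT replicate 4. A lipoprotein gene rose without WT replicate 1 or WT replicate 4, and an adipocyte or muscle marker fell without MIDY replicate 4 or WT replicate 1. In the cholesterol synthesis, heat shock, nuclear encoded oxidative phosphorylation, antioxidant and cell cycle lists 0 genes were called either way. Within the lists alone, 1 heat shock gene fell without MIDY replicate 1, 1 antioxidant gene rose without WT replicate 2, 1 bile acid gene fell without WT replicate 5 and 1 lipoprotein gene fell without MIDY replicate 3 or WT replicate 2. Camera's adjusted p was 0.324 for bile acids (median 0.10), 0.143 for hypoxia (0.07), 0.931 for xenobiotics (0.02), 0.911 for stress response (-0.05), 0.931 for retinoids (0.02), 0.306 for lipoproteins (0.05) and 0.927 for adipocyte and muscle (0.01). It was 0.931 for cholesterol synthesis (median -0.07), 0.540 for heat shock (0.04), 0.306 for oxidative phosphorylation (0.01), 0.156 for antioxidants (0.10) and 0.0584 for the cell cycle (-0.26). For xenobiotics and retinoids the mean lay below 0 while the median and camera's direction lay above it. Of the pancreas list only CPA1 was tested (0.69 ± 0.58 log2, SE; edgeR adjusted p = 0.605). Of the 13 genes in the list of mitochondrially encoded genes, 0 were found by symbol in the count table, so they were not analysed here.

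In all, camera with its preset correlation called 6 of 38 lists higher and 9 lower, while with an estimated correlation it called 0 of 38 (7 with an unadjusted p below 0.05). The test fry called 4 lists higher (peroxisomal and PPARA, urea, amino acid, periportal) and 2 lower (extracellular matrix, B and plasma cell). Among 100 splits of the 9 libraries into 4 and 5, the true one included, 32 gave at least 6 lists higher and 10 gave at least 9 lists lower, so the list counts are not set apart from those of other groupings. The gene counts were: no other split gave more than 1 gene in either direction.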

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

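In this part the tests of a uniform loss of non-hepatocyte cells, of WT replicate 2 and of more periportal tissue, and the list scores over all 38 lists and without WT replicate 2, and the total-count part of the scaling tests, were chosen only after the data or results were seen; the counts of splits, the RLE part of the scaling tests and the test of single libraries were planned before.

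Within-group gaps were checked in 196 groups of values (named genes, list scores and library measures), and 10 groups had 1 library far from the rest, where chance gives about 9.8 (1 in 20). WT replicate 1 had a low SFRP1 level (4.28 log2 CPM, against 5.03 to 5.09 in the other WT libraries). WT replicate 5 was low for IGFALS (5.38, others 5.60 to 5.68) and TBX3 (3.73, others 4.38 to 4.54), and MIDY replicate 2 was high for TBX3 (5.70, others 5.07 to 5.11). WT replicate 3 had the lowest TMM factor (0.90, others 0.997 to 1.03). MIDY replicate 4 was low for the score of peroxisomal oxidation and PPARA targets (-0.00157, others 0.20 to 0.22), and MIDY replicate 3 high for the insulin and IGF axis (0.19, others -0.08). WT replicate 2 stood high for the scores of bile acid genes (0.0447, others -0.24 to -0.19), pericentral markers (0.36, others -0.08 to 0.00238) and T and NK markers (0.74, others 0.04 to 0.16).

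Chance alone is argued against for the counts of genes and is not excluded for the counts of lists. Of 100 splits of the 9 libraries into 4 and 5, 1 (the true one) gave as many as 115 genes higher and 1 as many as 50 lower, and the highest other split gave 1 gene in each direction. These 100 are a part of the 126 possible splits, so no share below 1 of 100 could be seen. Splits that mix MIDY and WT animals also count any group difference as spread within groups, which lowers their gene counts. For the lists, 32 of 100 splits gave at least 6 higher (highest other split 12) and 10 of 100 gave at least 9 lower (highest other split 15). Camera's preset correlation treats list members as nearly independent, and list scores, which make no such assumption, left 0 of 38 lists past an adjusted p of 0.05 by exact permutation (13 with an unadjusted p below 0.05). In that test the amino acid, urea, periportal, T and NK and B and plasma cell scores each had the smallest p that the splits allow (0.00794, adjusted p = 0.0603), with every MIDY library on 1 side of every WT library. Because no p can lie below 0.00794, a list could pass over 38 lists only where several lists had low p together. Over a smaller family of 14 scores, of cell types, zones and differences between scores, also chosen after the results were seen, the T and NK, B and plasma cell and periportal scores and the periportal minus pericentral score passed (exact permutation, adjusted p = 0.0278), so whether these pass depends on the family.

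For the lower immune and stromal lists in MIDY, all 6 of the 6 called lists were still called lower under both RLE and total-count scaling. These were T and NK, B and plasma, endothelial, stellate, cholangiocyte and extracellular matrix. Camera compares a list with all other genes, so a shift shared by all genes largely cancels and these calls cannot test scaling. The matrix median was -0.36 under total counts against -0.38, so it moved little with the scaling. The calls of 2 single matrix genes became 0 under total counts, although the fold changes of both also moved little. Without WT replicate 2, 5 of the 6 were still called by camera, all 5 lists other than cholangiocyte, whose median was -0.57 against -0.55 with all libraries (adjusted p = 0.120). There 4 list scores still differed at 0.0286, the smallest p that an exact permutation of 8 libraries can give (T and NK, B and plasma, endothelial, extracellular matrix), while the stellate and cholangiocyte scores did not (0.0857 and 0.257), and the unadjusted p with an estimated correlation was 0.00868, 0.0415, 0.119, 0.0503, 0.0798 and 0.420 for these 6 lists in that order, so the share of this library cannot be told apart for the group as a whole. A uniform loss of all non-hepatocyte cells cannot be told apart from a loss of some types: the MIDY minus WT difference of the T and NK score lay below that of the endothelial score (by -0.33, 95% interval -0.79 to 0.025, exact permutation p = 0.0794), which 4 and 5 animals leave undecided. The endothelial score also mixes opposite changes, since adjusted over the list alone 2 of its markers fell and 1 rose. Genotype and insulin treatment remain untested as a biological source, and chance is not excluded for the number of lower lists.

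The lower interferon and antigen presentation list was weighed against WT replicate 2, which had the highest score, and the influence of this library cannot be told apart from a difference between the groups. Without it camera still called the list lower (median -0.40 against -0.66, adjusted p = 1.9e-07), but with an estimated correlation the unadjusted p was 0.161 and the score difference of -0.46 had an exact permutation p of 0.0857. With all libraries the list had an adjusted p = 0.416 with an estimated correlation, and MIDY replicate 2, with a score of 0.14, lay above 2 of the WT libraries. What sets the level of these genes in single animals, such as a past infection, was not tested.

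The higher amino acid and periportal lists may reflect more periportal tissue in the MIDY pieces, 1 library, the scaling or the diabetic state. More periportal tissue cannot be told apart from a change within hepatocytes: the pericentral score differed by -0.0875 (95% interval -0.36 to 0.165, exact permutation p = 0.5), but its members went both ways (median -0.25, quartiles -0.63 and 0.28), which decides nothing. The pericentral marker GLUL was among those lower and TBX3 among those higher. The 40 amino acid and urea genes outside both zone lists were higher as a set (camera p = 8.3e-09, p = 0.0125 with an estimated correlation). Their score was 0.36 higher in MIDY on the log2 scale (95% interval 0.225 to 0.49, exact permutation p = 0.00794). The 7 periportal genes outside the amino acid and urea lists were higher by camera too (p = 0.00212, p = 0.116 with an estimated correlation). Genes outside a short marker list can still be zoned. A single library as the whole cause is argued against, since the scores of both lists separated all MIDY from all WT libraries. At the preset correlation camera also called both lists higher in all 9 fits that left out a library. With an estimated correlation and all libraries, both had a camera adjusted p = 0.246. Both (2 of 2) were called under RLE and total-count scaling too. A shift shared by all genes largely cancels in camera, so these calls cannot test scaling. The median log2 fold change of all genes was -0.00465 with TMM, -0.00692 with RLE and 0.018 with total counts. The list medians of 0.31 and 0.57 are far larger, which argues against the choice among these scalings as their source. Whether amino acid breakdown was raised in MIDY livers stays open, with genotype and insulin treatment confounded.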

How the results depend on the processing

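Leaving out WT replicates 1 and 2 together and total-count scaling for the lists were chosen only after the data were seen; all other alternatives were planned. RLE factors, total counts, the 10 most abundant genes out, no filter and the stricter filter kept both gene counts within 1.5 times of 115 higher and 50 lower. DESeq2 called 355 higher and 284 lower, including all 165 main calls; voom called 81 lower and 1 surrogate variable 79 lower. Without 1 library the count of higher genes ran from 34 (without MIDY replicate 2) to 152 (without WT replicate 1) and that of lower genes from 4 to 107 (the same libraries). Without WT replicates 1 and 2 it was 42 higher and 24 lower, 40 of them among the 165. The cause of these differences was not tested. None of the 165 calls changed sign under any of these settings. The median log2 fold change of all genes was -0.00465 with TMM, -0.00692 with RLE and 0.018 with total counts.

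For the lists, an estimated correlation left 0 higher and 0 lower, and fry 4 higher and 2 lower; without 1 library 4 to 8 were higher and 8 to 10 lower. The cholesterol synthesis list, not called with all libraries (median -0.07), was called higher without WT replicates 1 and 2 (median 0.20, camera adjusted p = 0.00369); the cause was not tested. Values never called that changed sign were counted as kept (8 for genes, 43 for lists). At this depth and number of animals 13.4% of simulated 1.5-fold changes were recovered, so a gene not called here is not shown to be unchanged.

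Counts of called list members moved as well, without a cause that was tested. Given here are moves of over 1.5 times by at least 3 genes or in the matrix list. The ketone body list is left out, since its counts of called genes are not reported here. Over all genes DESeq2 called 9, voom 4 and total counts 0 matrix genes lower, against 2 in edgeR and 0 without WT replicates 1 and 2. DESeq2 called 6 interferon (2), 4 circadian (0) and 3 pericentral genes lower (0), and 4 peroxisomal and PPARA genes higher (1). Adjusted over the list alone DESeq2 called 16 interferon genes lower (5), 7 stellate (0), 4 T and NK (1) and 3 Kupffer cell markers (0). The interferon count was 10 with voom and 8 with total counts, and the matrix count 6 with total counts (13). In the same adjustment 4 cholangiocyte (1) and 3 stellate markers (0) fell and 3 fatty acid oxidation genes (0) rose with 1 surrogate variable. Without WT replicates 1 and 2, 3 amino acid (8) and 2 periportal genes (6) rose over all genes. Within the lists alone 6 matrix (13), 11 interferon (5), 6 pericentral (3) and 3 immediate early genes (0) then fell and 5 lipid synthesis genes (2) rose.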

Other observations

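The circadian grouping below was tested as a list fixed beforehand; describing these genes together was chosen only after the results were seen.

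Clock genes are set by the time of day and by feeding. Of 19 measured clock genes 0 were called over all genes tested with edgeR (2 rose and 6 fell adjusted over the list alone). Over all genes 2 rose and 1 fell without WT replicate 1, and DESeq2 called 1 higher and 4 lower with all libraries. The counts depended on other libraries too: adjusted over the list alone 0 rose and 1 fell without MIDY replicate 3, and the same without MIDY replicate 4. Without WT replicate 5, 1 rose and 2 fell, and 1 rose in place of 2 without MIDY replicate 2, WT replicate 2, WT replicate 3 or WT replicate 4. Those lower were CIART (-1.70 ± 0.38), DBP (-0.79 ± 0.23), PER1 (-0.38 ± 0.12), NR1D2, CRY2 and PER3, and CRY1 was among those higher (0.49 ± 0.18, log2 ± SE; edgeR adjusted p over all genes from 0.0528 for CIART to 0.215 for CRY1). CRY1, CRY2, NR1D2 and PER3 were named after their values were seen. Camera did not call the list (median -0.17, adjusted p = 0.225; adjusted p = 0.459 with an estimated correlation). The time at which each liver was taken was not used here.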
